A study of Mus musculus with 5 samples.

How the data were processed

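The 5 samples were mouse embryonic stem cell-derived cells, 1 per group: day 5, day 6 and day 8 without MPA, and day 6 and day 8 with 2 µM MPA. Groups, days and the dose were taken from the labels. Per the labels' protocols, biotin-labelled cRNA was made from 100 ng of total RNA with a 3' IVT kit and hybridised to an Affymetrix mouse expression array, 1 per sample. The authors deposited 1 linear intensity per probe set and array. Per the submitters' processing notes the tool was MAS5, whose version, background setting and filters are not given in the sources used here. The values show a 2% trimmed mean of 500 on each of the 5 arrays. MAS5 signals of dim probe sets are noisy on a log scale, and the bacterial control probe set trpnX, a target that the cells lack, reached a signal of 59.4.

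Of 45101 probe sets, 64 were controls. The remaining ones were named through the platform annotation given, in which 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. Probe sets with several symbols or none were left out. Of the 34945, 34741 matched the RefSeq gene table (assembly GRCm38.p6, used for names only) by gene identifier, and 0 symbols needed updating. This gave 18193 genes, 9010 of them with several probe sets. Each gene was represented by the probe set with the highest mean signal over the 5 arrays, and the other probe sets above the floor were checked for the same direction.

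Signals were taken to log2 after raising those under a floor, the median of all non-control probe sets over the 5 arrays (86.8), to that floor. A gene counted as measured in a comparison where at least 1 of the 2 arrays lay above the floor. A fold with 1 array at the floor is a lower bound and is written "at least", and no fold is given with both at the floor. With 1 array per group no test applies to a difference of 2 arrays, and genes 2-fold or more apart were counted. Fold sizes of dim genes are understated by the floor.

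The planned test used the 4 arrays of days 6 and 8, with day as a factor and MPA as a term, which leaves 1 residual degree of freedom. It ran on genes above the floor on at least 2 of the 4 arrays, in limma 3.58.1 (R 4.3.3) with lmFit and eBayes (trend and robust), Benjamini-Hochberg adjusted p under 0.05. Its error is the disagreement between the MPA differences of both days, so it finds differences that are alike at both days, and it does not measure the spread between cultures. The fit was tested on simulated data, with 63, 59 and 78 genes changed by a log2 of 1, 2 and 3. It called 25.4%, 79.7% and 89.7% of them, and 6 of 11399 unchanged genes. The simulated changes were the same at both days, with an error of 1 size per decile of signal. The shares called need not hold for these arrays, where the error may vary by gene and MPA differences may change between the days. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

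There were 37 gene lists, fixed before the data were examined along with the comparisons, the main settings and the rule for named genes. Of their 659 genes, 590 matched a gene of the array. The lists hold markers of cell types that the cultures could contain and pathways, and some share genes. A list's median log2 difference was placed among 10000 random lists of the same size matched on mean signal (deciles), as a percentile that describes these arrays and is no p-value. A list stood outside the central 95% under percentile 2.5 or above 97.5. At day 6 this held for 14 of 36 lists and at day 8 for 20 of 37, where 1.8 and 1.85 lists of randomly drawn genes would. In the controls it held for 15 of 36 lists for day 6 against 5. For day 8 against 5 it was 15 of 36, and for day 8 against 6 it was 11 of 36. Members of a list can move together between any pair of cultures, so this excess does not by itself show an MPA effect. Which members count as measured was settled after a first look at list medians under another rule, members above the floor on at least 2 of the 4 arrays. In the limma fit, members were counted as adjusted over all genes and as adjusted over the list alone.

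Named genes were the 10 highest and 10 lowest by mean MPA difference among genes 2-fold apart the same way at both days, the 5 highest and 5 lowest at each day among genes above the floor on both arrays, the 10 highest and 10 lowest of day 8 against day 5 in the controls, up to 4 members per list with the largest mean MPA difference and up to 4 with the largest control difference, and 15 genes fixed by name. Not every gene that the rule allows is printed.

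The alternatives were quantile normalization, median centring over genes above the floor on all 5 arrays, floors at the 25th and 65th percentiles, log2(signal + floor), the mean over a gene's probe sets, and leaving out probe sets whose names end in _s_at, _x_at or _a_at. For the limma fit they were also day as a straight line over all 5 arrays, no day term, eBayes without trend and robust, and no filter. Mean list differences were also taken with 1 day only, and the correlation of both MPA differences over genes above the floor on all 4 arrays. A floor at the 75th percentile and the other membership rule were added after seeing the data, as was the comparison of MPA day 8 with MPA day 6. A limma fit over all 5 arrays, with day as a straight line and the MPA difference free at each day, was also added then, to test the difference between the days. It leaves 1 residual degree of freedom, its error is the departure of the controls from a straight line, and its alternatives were those of the normalization, floor, log scale and probe sets. On simulated data it called 50%, 98.7% and 98.6% of 54, 76 and 70 genes whose difference changed by a log2 of 2, 4 and 6, and 35 of 11399 unchanged genes. In that simulation the controls followed a straight line, with an error of 1 size per decile of signal and no floor. The shares called there need not hold for these arrays, where the controls may bend by gene. Correlations across genes used only differences that share no array.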

Results

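Gene expression was measured in mouse embryonic stem cells that were taken towards a pancreatic fate on gelatin-coated plates. Cells were collected at day 5, at day 6 and at day 8, and MPA was given to part of the day 5 cells at 2 µM, so that treated cells had been exposed for 1 day at day 6 and for 3 days at day 8. MPA is named here as the labels name it, and the labels do not write it out. The 5 groups were day 5, day 6 and day 8 without MPA (the controls), and day 6 and day 8 with MPA. Each group had 1 array, so the data hold no replicates and no value carries a spread between cultures. A difference between a pair of arrays is therefore given as a size, without a test, and the number of arrays limits its precision.

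Each array held 45101 probe sets, and its signal was scaled to a 2% trimmed mean of 500. The median signal was 86.8 at day 5, 86.5 in the day 6 control, 78.3 with MPA at day 6, 94.5 in the day 8 control and 93.5 with MPA at day 8. Signals under 86.8, the median of all non-control probe sets, were raised to that floor. Between 46.7% (MPA, day 6) and 51.9% (control, day 8) of the probe sets lay above it. Control and MPA arrays of a day correlated across genes at r = 0.960 at day 6 and 0.962 at day 8, against 0.903 for day 5 with the day 8 control. The 3'/5' signal ratio of Gapdh, a sign of RNA integrity, was 1.08, 1.19, 1.31, 1.55 and 1.57 in the same order, and that of Actb was 2.08, 3.04, 3.06, 2.81 and 2.71.

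The controls show which genes differed as differentiation went on without MPA. From day 5 to day 8 many genes of the pluripotent epiblast were lower. Pou5f1 and Nanog, transcription factors of the pluripotent state, were 79.2-fold and at least 64.2-fold lower. Tdgf1, Lefty1 and Nodal, of the Nodal pathway, were at least 191-fold, at least 129.8-fold and 43.8-fold lower, and the epiblast genes Fgf5 and Otx2 at least 58.8-fold and at least 49.97-fold lower. The apelin receptor gene Aplnr was at least 109-fold lower, Trh at least 51.7-fold lower and L1td1 46.1-fold lower. Eomes, a transcription factor of early mesendoderm, was 30.4-fold lower. The pluripotency list had a median log2 difference of -0.47 over 16 measured members (percentile 0.75), of which 11 were lower and 5 higher, among the latter Klf4, at least 7.75-fold higher. The definitive endoderm list had a median of -2.83, with 15 of 17 members lower (percentile 0). Over the alternatives these medians ran from -2.53 to -0.47 and from -2.94 to -1.06. Percentiles place a list among random lists matched on signal and describe these arrays only.

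Genes of the retinoic acid response and of the Hox clusters were higher at day 8. The retinoic acid receptor gene Rarb was at least 45.1-fold higher at day 8 than at day 5, and Hoxc5, Hoxc4 and Hoxa5 were at least 47.53-fold, 20.6-fold and at least 19.4-fold higher. Crabp2, which encodes a retinoic acid-binding protein, was 29.47-fold higher, and the transcription factor genes Tshz1 and Nr2f1 were 57.9-fold and at least 55.6-fold higher. The median of the retinoic acid and Hox list was 2.54, with 15 of 16 members higher (percentile 100). Markers of several later cell types were higher too. The list medians were 2.33 for cardiac muscle (Myh7 at least 10.2-fold higher), 2.02 for neural genes (Zic1 18.9-fold higher), 1.64 for endocrine genes and 1.47 for mesenchyme and fibroblasts (Col3a1 22.8-fold and Snai2 at least 27.1-fold higher), each at percentile 100. The endocrine hormone genes Ghrl, of ghrelin, and Sst, of somatostatin, were at least 25.6-fold and at least 8.38-fold higher. The hepatic and the extraembryonic endoderm lists had smaller medians of 0.46 and 0.53 (percentiles 98.2 and 99.2), with Ttr, the gene of transthyretin, at least 14.2-fold higher. Over the alternatives the medians ran from 1.14 to 2.78 for cardiac muscle, 0.68 to 2.02 for neural, 0.82 to 2.53 for endocrine, 0.90 to 1.73 for mesenchyme, 0.26 to 1.49 for hepatic and 0.43 to 0.95 for extraembryonic endoderm genes.

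Metabolic genes also differed between day 5 and day 8. All 17 measured glycolysis and hypoxia genes were lower (median -1.70, percentile 0), among them the hypoxia-induced Egln3, 29.4-fold lower. All 14 cholesterol synthesis genes were lower as well (median -0.89, percentile 0). The interferon response list had a median of -1.18, the FGF and ERK target list one of -0.68 and the mitosis list one of -0.47 (percentiles 0.01, 0.01 and 0.06), while the cell cycle inhibitor list stood at 0.57 (percentile 99.4), with ranges over the alternatives of -1.93 to -0.32 for the first and 0.03 to 0.57 for the last. In all, 1228 genes were at least 2-fold higher and 929 at least 2-fold lower at day 8 than at day 5, out of 12784 measured. The excess of higher genes depends on the scaling. Quantile normalization gave 1065 higher and 1072 lower, and median centring 1066 higher and 1108 lower. Of the 2-fold genes with a second probe set, 84.0% went the same way there. The Gapdh 3'/5' ratio was higher at day 8 than at day 5 alongside these groups (1.55 against 1.08), and the counts depend on the floor: at a floor on the 25th percentile they summed to 6225 in place of 2157.

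The first day of the control time course already held much of the retinoic acid difference. From day 5 to day 6 the retinoic acid and Hox list had a median of 2.49 (percentile 100), the definitive endoderm list -1.11 and the ribosome biogenesis list -0.47, with 24 of its 25 members lower (percentile 0 for both). Mitosis genes were higher at this step, by a median of 0.31 (percentile 99.9), and so were genes of the unfolded protein response, by 0.37 (percentile 99.7). Of the other lists, pluripotency stood at -0.65, FGF and ERK targets at -0.86, interferon response at -1.13 and cholesterol synthesis at -0.46 (percentiles 0.05, 0, 0.01 and 0). In all, 689 genes were 2-fold higher and 555 2-fold lower, out of 12611. From day 6 to day 8 the markers of later cell types had medians of 1.85 for cardiac muscle, 1.85 for neural, 1.71 for endocrine and 1.06 for mesenchymal genes, each at percentile 100. BMP and TGF-beta targets stood at 0.72 and ribosome biogenesis genes at 0.33 (percentiles 99.98 and 99.9), the latter with 24 of 25 higher, opposite to the step before. The BMP and TGF-beta targets went both ways, with 11 of 17 higher and 6 lower, and their mean was -0.25. Definitive endoderm genes stood at -0.88, with 13 of 16 lower, and cholesterol synthesis genes at -0.63, with 13 of 14 lower (percentile 0 for both). At this step all 17 glycolysis and hypoxia genes (median -1.49) and all 23 mitosis genes (median -0.70) were lower, both at percentile 0. It gave 907 genes 2-fold higher and 825 2-fold lower, out of 12824. This split turned under both other scalings, to 770 higher and 963 lower with quantile normalization and 763 higher and 1008 lower with median centring.

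The comparison of MPA with control at both days asks which genes differed in the same direction after 1 and after 3 days of exposure. Fgfbp3, which encodes a binding protein for fibroblast growth factors, was the gene with the clearest difference. Its signal was 4679.7 without and 682 with MPA at day 6, and 1925 without and 209.9 with MPA at day 8 (1 probe set). Averaged over both days its expression fell by 2.99 on the log2 scale (SE 0.27, adjusted p 0.0229 in the limma fit, lower at both days). It was the only one of 11599 genes to pass, and the next lowest adjusted p was 0.344. At an unadjusted p under 0.05 there were 739 genes, 391 higher and 348 lower, where 580 would be expected by chance. The fit has 1 residual degree of freedom and counts a difference between the days as error, and Fgfbp3 did not pass under 7 of the alternatives, with an adjusted p from 0.00877 to 1 over all of them.

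Of the lists that stood apart in the same direction at both days, the neural one had the largest medians. Of the 15 measured at day 8, all 15 were lower with MPA, with a median log2 difference of -1.55 (percentile 0). At day 6, 10 of 13 were lower, with a median of -0.94 (percentile 0.01). Zic1, a transcription factor gene of the dorsal neural tube, was at least 3.70-fold lower at day 6 and 21.7-fold lower at day 8, with a signal of 4188 without and 193 with MPA at day 8. The proneural gene Neurog1 was at least 3.95-fold and at least 17.96-fold lower, and Pax3, a gene of the dorsal neural tube and neural crest, 3.35-fold and 4.60-fold lower. Hes5, a Notch-responsive gene of neural progenitors, was at least 2.61-fold and at least 9.39-fold lower. Pax6 was 3.29-fold and 2.93-fold lower on its brightest probe set, while 1 of its 2 further probe sets above the floor went the other way at day 6 and 1 of 3 at day 8. Adjusted over the list alone, 8 of the 15 neural members passed the limma test, all lower, against 0 adjusted over all genes. The list-alone count was 3 with the mean over probe sets and 0 with a floor at the 75th percentile, and the list median ran from -1.05 to -0.32 at day 6 and from -1.67 to -0.69 at day 8 over the alternatives.

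Several further genes were among the 10 with the lowest mean MPA difference of those 2-fold lower at both days. The radial glia transcription factor gene Rfx4 was 2.36-fold lower at day 6 and at least 10.4-fold lower at day 8, and the endothelin receptor gene Ednrb, used by neural crest cells, 2.03-fold and 12.7-fold lower. Fgf15 was 5.32-fold and at least 3.52-fold lower. Crabp2, of a retinoic acid-binding protein, was 2.49-fold and 6.85-fold lower. Hoxb5os, an antisense transcript of the Hoxb cluster, was 9.31-fold and 4.16-fold lower. Crabp1, of the other such binding protein, which is not among the 10, was 2.56-fold and 4.74-fold lower. The retinoic acid and Hox list as a whole had a median of -0.61 at day 6, with 16 of 17 members lower (percentile 0), and of 0.08 at day 8 (percentile 79.5). Adjusted over the list alone, Crabp1 and Crabp2 passed the limma test, both lower, against 0 over all genes, and the list-alone count ran from 1 to 4 over the alternatives. Sox2 passed, lower, as the 1 member of the pluripotency list, whose medians were 0.16 and 0.12 (percentiles 75.8 and 75.7; -0.20 to 0.16 and -0.55 to 0.20 over the alternatives). Hes5 was the 1 member to pass, lower, of the Notch signalling list, whose medians were -0.22 and 0.22 (percentiles 4.59 and 95.3; -0.33 to -0.08 and -0.31 to 0.23 over the alternatives). Over all genes 0 members of either list passed, and over the alternatives the list-alone counts ran from 1 to 2 for pluripotency and from 0 to 1 for Notch signalling.

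Targets of p53, the transcription factor of the DNA damage and nucleolar stress responses, were higher with MPA at both days. Their median was 0.77 at day 6, with 20 of 22 members higher (percentile 100), and 0.32 at day 8, with 15 of 23 higher (percentile 99.9). Cdkn1a, the gene of the cell cycle inhibitor p21, was 2.19-fold higher at day 6 and 2.28-fold higher at day 8. Plk2 was 2.81-fold and 2.005-fold higher, Trp53inp1 2.501-fold and 1.86-fold higher, and Perp 2.45-fold and 1.55-fold higher. Adjusted over the list alone, 6 of 22 members passed, all higher, against 0 over all genes. The list-alone count ran from 1 to 7 over the alternatives, with 1 under the mean over probe sets, and the median ran from 0.66 to 0.77 at day 6 and from 0.23 to 0.42 at day 8 over the alternatives. The list of cell cycle inhibitors, which shares Cdkn1a, had a median of 0.58 at day 6 and 0.04 at day 8 (percentiles 99.9 and 65.1; 0.18 to 0.63 at day 6 over the alternatives). Its members went both ways at day 6, 7 of 13 higher and 6 lower. Of its members, Cdkn1a and Cdkn2b passed adjusted over the list alone, both higher, against 0 over all genes and a list-alone range of 1 to 2, and Cdkn2b was 3.63-fold and 1.69-fold higher. Apoptosis genes had a median of 0.37 at day 6, with 14 of 17 higher (percentile 99.1; 0.25 to 0.60 over the alternatives; Bcl2l11 2.85-fold higher) and of 0.01 at day 8 (percentile 59), with 0 members past either adjustment.

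Epithelial genes were higher with MPA, in 11 of 15 members at day 6 (median 0.31, percentile 99.6; 0.19 with median centring) and in all 16 at day 8 (median 0.85, percentile 100). The keratin genes Krt7 and Krt18 were 1.60-fold and 1.25-fold higher at day 6 and 2.61-fold and 1.76-fold higher at day 8. The tight junction genes Cldn4 and Ocln were 2.84-fold and 1.42-fold higher at day 6 and 1.81-fold and 3.54-fold higher at day 8, although the other probe set of Ocln went the opposite way at day 6. Definitive endoderm genes had a median of 0.20 at day 6 and 0.64 at day 8 (percentiles 90.5 and 100), with 12 of 17 and 10 of 13 members higher and a range of 0.26 to 0.76 at day 8 over the alternatives. Foxa1 and Foxa2, transcription factors of the endoderm, were 1.51-fold and 1.62-fold higher at day 6 and 2.21-fold and 1.93-fold higher at day 8. The endoderm markers Sox17 and Cxcr4 went the other way at day 8, with log2 differences of -1.68 and of -2.40 or beyond. They were the 2 endoderm list members 2-fold lower at that day, against 1 that was 2-fold higher, and the mean of the list was 0.18. Adjusted over the list alone, 7 of 15 epithelial members passed, all higher, and so did 3 of 15 endoderm members, Foxa1, Foxa2 and Cdh1, the last shared by both lists. Over all genes 0 passed in either list. The list-alone counts ran from 2 to 7 and from 0 to 3 over the alternatives.

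Genes of amino acid supply were lower with MPA at both days. The list of the amino acid and integrated stress response had a median of -0.75 at day 6 and -0.45 at day 8, both at percentile 0, with 16 of 19 and 13 of 19 members lower. Its 4 members that passed the limma test adjusted over the list alone were all lower, against 0 over all genes and 3 to 4 over the alternatives. They were the amino acid transporter gene Slc7a5, 3.60-fold and 1.86-fold lower, the serine and folate pathway genes Psat1, 1.97-fold and 1.71-fold lower, and Mthfd2, 2.58-fold and 1.75-fold lower, and Asns, of asparagine synthetase, which was named after its values were seen, with log2 differences of -1.06 and -0.65. The unfolded protein response list had medians of -0.42 and -0.30 (percentiles 0.02 and 0.39; -0.53 to -0.20 at day 6 over the alternatives), with the chaperone cofactor gene Sdf2l1 1.91-fold and 2.02-fold lower. Of its members 0 passed either adjustment, with a list-alone range of 0 to 2 over the alternatives.

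**Figure D1:**
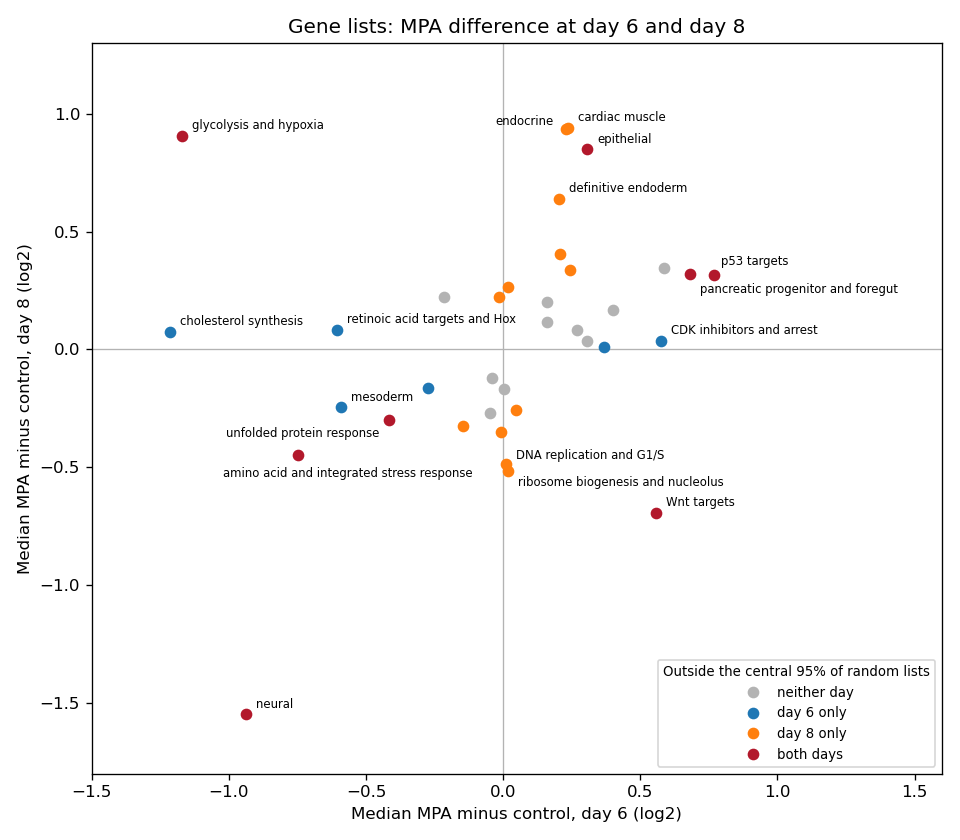
Median log2 difference of MPA minus control for each gene list, at day 6 on the horizontal axis and at day 8 on the vertical axis. Each point is 1 list measured at both days, coloured by whether its median lay outside the central 95% of random lists at neither day, at 1 day or at both days; the neural list lies lowest at day 8 (-1.55), and the glycolysis and hypoxia list lies at -1.17 at day 6 and 0.91 at day 8.

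Of the genes at least 2-fold higher at both days, Sct, of the gut hormone secretin, had the largest mean difference, 5.53-fold at day 6 and 3.003-fold at day 8. Neurod1, a transcription factor gene of endocrine and neuronal cells, was 2.55-fold and 3.38-fold higher. The epithelial cytoskeletal linker gene Eppk1 was at least 2.39-fold and 3.85-fold higher. The remaining 7 of the 10 were Slc43a2, Hmgcll1, Rps27, Lurap1l, Glipr1, Tent5a and Mif4gd, and the other probe set of Slc43a2 went the opposite way at day 6. There were 39 genes 2-fold higher and 49 2-fold lower at both days, of 11007 measured at both. Independent lists of these lengths would share 20.96 and 14.03. The sum of both counts, 88, depends on the floor, with 1040 at the 25th and 34 at the 65th percentile. Independent lists would give 34.99 for this sum. Genes 2-fold apart in opposite directions at the 2 days showed a like excess, 80 against 34.3. The excess in the same direction therefore does not by itself show an MPA effect shared by both days.

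After 1 day of MPA, genes of glycolysis and hypoxia and of cholesterol synthesis stood furthest from control. All 17 measured glycolysis and hypoxia genes were lower (median -1.17, percentile 0), among them Bnip3, a mitophagy gene induced by hypoxia, 4.89-fold lower, Ankrd37, 4.87-fold lower, and Hk2, of hexokinase 2, 3.26-fold lower. All 14 cholesterol synthesis genes were lower (median -1.21, percentile 0), among them Lss, of lanosterol synthase, 4.45-fold lower, and Mvd, Dhcr7 and Fdps, 2.56-fold, 2.55-fold and 2.37-fold lower. Outside these lists, Aldoc, the gene of aldolase C, was 7.89-fold lower, the acetyl-CoA synthetase gene Acss2 5.89-fold lower and the immediate early gene Ier3 5.38-fold lower. At day 8 the cholesterol list stood at 0.08 (percentile 87), with 9 of 14 members higher. No member of either list passed either adjustment in the limma fit, which counts a difference between the days as error and so bears little on either list.

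Other groups were higher or lower at day 6. Genes of the pancreatic progenitor and foregut list had a median of 0.68, with 8 of 13 higher (percentile 99.9), with Onecut2 1.82-fold and Shh 1.60-fold higher, but that median turned to -0.22 and -0.26 with floors at the 65th and 75th percentiles. At day 8 it was 0.32 (percentile 97.6), with 13 of 16 members higher and a range of 0.32 to 0.92 over the alternatives. Sox9, a progenitor gene, was 1.92-fold higher at day 6 and 2.43-fold at day 8, with its other probe set going the opposite way at day 6. Mesoderm genes had a median of -0.59 at day 6 (percentile 0.13) and -0.25 at day 8 (percentile 7.54), and over the alternatives these ran from -1.23 to -0.47 and from -0.29 to 0.90, above 0 at day 8 with a floor at the 75th percentile. Meox1 and Tcf15, somite genes, were 4.36-fold and 2.04-fold lower at day 6 and 1.74-fold and 2.41-fold lower at day 8, and passed the limma test adjusted over the list alone, against 0 over all genes and a list-alone range of 0 to 2 over the alternatives. Cytosolic ribosomal protein genes had a median of -0.27 at day 6 (percentile 1.61; 0.02 under quantile normalization) and -0.16 at day 8 (percentile 11.1). No member of the pancreatic or the ribosomal protein list passed either adjustment. The intermediate filament gene Synm was 9.54-fold higher at day 6, Ttr 7.06-fold, and Zfp365, 1700007K13Rik and Cyyr1 7.12-fold, 7.32-fold and 6.93-fold higher. At day 6 the counts were 492 genes 2-fold higher and 385 2-fold lower with MPA, out of 12240. Median centring of the arrays turned this split to 363 higher and 534 lower, or 40.5% in place of 56.1% higher, and moved the median difference of all genes from 0.02 to -0.08, so that list medians at day 6 are to be read against a shift of that size. The Gapdh 3'/5' ratio was 1.31 with and 1.19 without MPA at this day. Of the 2-fold genes of this day with a second probe set, 73.4% went the same way there, and 25.1% were 2-fold apart that way.

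After 3 days of MPA, most measured endocrine and cardiac markers were higher. Gcg, the gene of glucagon, had a signal of 271 without and 2572 with MPA, 9.49-fold higher, and Neurog3, the transcription factor gene of endocrine progenitors, 193 and 1295, 6.71-fold higher. Both lay under the floor on the day 6 arrays. Ghrl was 1.54-fold higher, while Sst was 2.91-fold lower. The endocrine list had a median of 0.94 at day 8, with 12 of 14 members higher (percentile 100; 0.62 to 1.72 over the alternatives), and of 0.23 over 5 members at day 6 (percentile 73.8; -0.10 to 0.58). Adjusted over the list alone, Neurod1 and Chga passed, higher, and Pax6, which the neural list shares, passed, lower, against 0 over all genes. Chga, of chromogranin A, was named after its values were seen and had log2 differences of 1.29 at day 6 and 1.25 at day 8. The list-alone count ran from 0 to 5 over the alternatives. Cardiac muscle genes had a median of 0.94 at day 8, with 9 of 10 higher (percentile 99.99; 0.46 to 1.02 over the alternatives; Actc1 3.53-fold higher), and 0.24 at day 6 (percentile 86.1; 0.11 to 1.10). Mesenchymal genes went both ways, with 11 of 17 higher and 6 lower at day 8, and had medians of 0.40 at day 8 and 0.21 at day 6 (percentiles 99.9 and 93; 0.22 to 0.42 at day 8 over the alternatives), with Tagln, a smooth muscle gene, 2.57-fold higher at day 8. In neither of these lists did a member pass, with a list-alone range of 0 to 1 over the alternatives for cardiac muscle.

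Cell growth and division genes were lower after 3 days of MPA. Of 25 ribosome biogenesis and nucleolus genes, 22 were lower at day 8 (median -0.52, percentile 0), against a median of 0.02 at day 6 (percentile 60). Rrp9, of ribosomal RNA processing, was at least 2.86-fold lower and Polr1b, of RNA polymerase I, 2.07-fold lower. Of 25 DNA replication and G1/S genes, 23 were lower (median -0.49, percentile 0; 0.01 at day 6, percentile 56.9), with the cyclin genes Ccnd1 and Ccne1 3.54-fold and 2.46-fold lower. Of 23 mitosis and G2/M genes, 20 were lower at day 8, with medians of -0.32 at day 8 and -0.15 at day 6 (percentiles 0.03 and 6.62), with Aurkb 1.77-fold lower. Genes of purine synthesis and GTP supply had a median of -0.35 at day 8, with 15 of 18 lower (percentile 0.02), and of -0.01 at day 6 (percentile 51.2). Prps1, of phosphoribosyl pyrophosphate synthesis, was 2.21-fold lower and Atic, of the last steps to IMP, 1.89-fold lower. Impdh1, of IMP dehydrogenase, was 2.002-fold higher at day 6 and 1.17-fold lower at day 8, and Impdh2 was not analysed here. Of 14 pyrimidine and deoxynucleotide genes, 10 were lower at day 8, with medians of -0.26 and 0.05 (percentiles 2.11 and 62.5), with the thymidine kinase gene Tk1 3.48-fold lower at day 8. In the limma fit 0 members of these 5 lists passed either adjustment, but the list-alone count ran from 0 to 2 over the alternatives for purine synthesis and GTP supply. The fit counts a difference between the days as error, so it bears little on lists that stood apart at day 8 only.

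Among single genes at day 8, the neural transcription factor gene Pou3f3 was 14.7-fold lower, Msx1 9.33-fold lower and Fabp7, of the brain fatty acid-binding protein, at least 21.2-fold lower. Bnip3 was 7.40-fold higher, the chemokine gene Cxcl12 7.22-fold higher and Shisa3 7.13-fold higher. The counts at day 8 were 469 genes 2-fold higher and 401 2-fold lower, out of 12599. They summed to 870, against 4774 with a floor at the 25th percentile and 507 with the mean over probe sets.

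**Figure D2:**
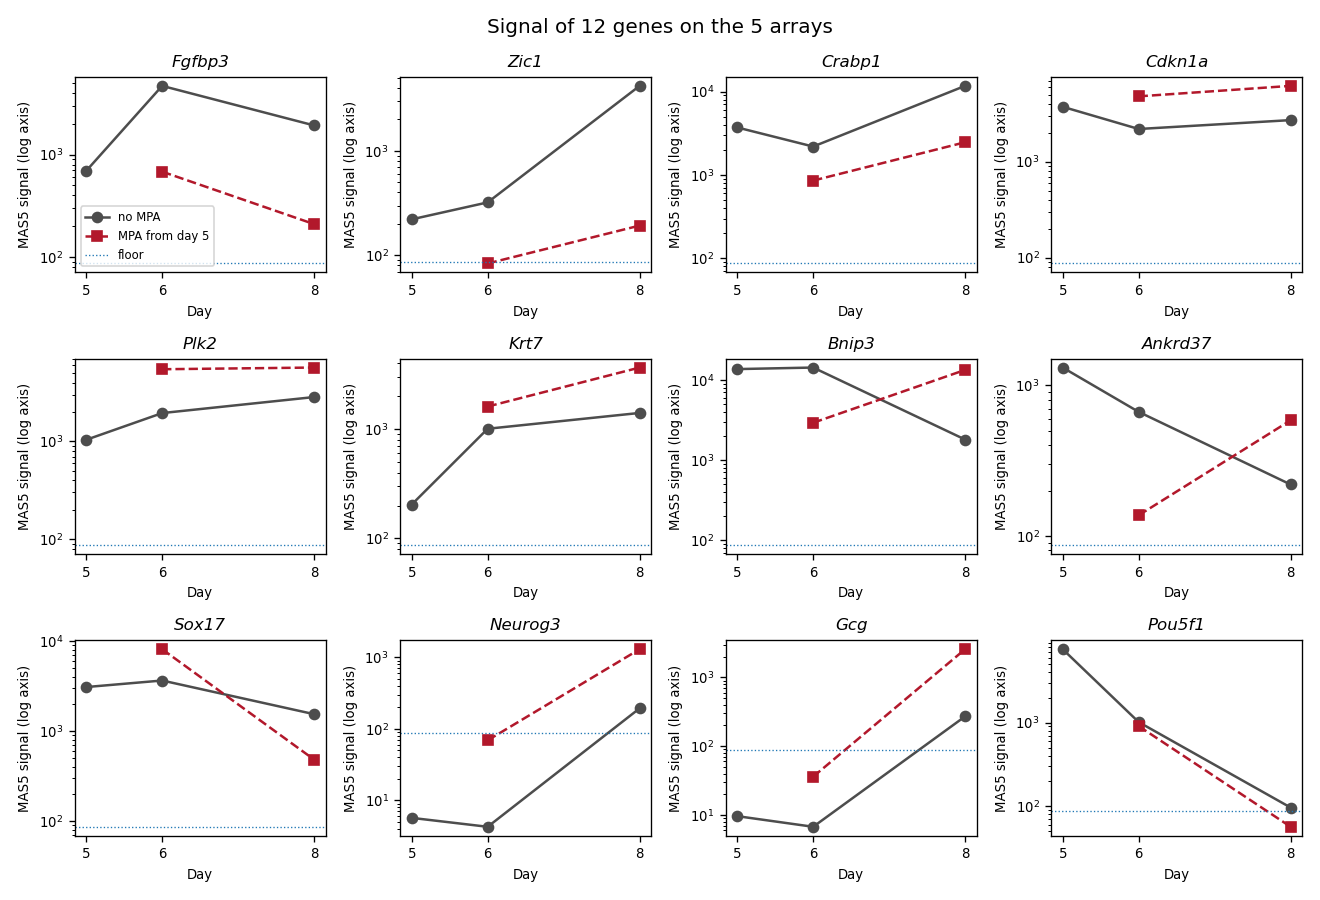
Array signal (log axis) of 12 genes at days 5, 6 and 8; grey lines join the arrays without MPA, red dashed lines join the day 6 and day 8 arrays with MPA, each point is 1 array and the dotted line is the floor of 86.8. Fgfbp3, Zic1 and Crabp1 lie lower and Cdkn1a, Plk2 and Krt7 higher with MPA at both days, and Bnip3 lies at 2921 against 14278 at day 6 and at 13338 against 1803 at day 8.

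Part of the genes differed in opposite directions at the 2 days. All 17 glycolysis and hypoxia genes were lower at day 6, and 16 of 17 were higher at day 8 (median 0.91, percentile 100). Bnip3 was 4.89-fold lower and then 7.40-fold higher. Pfkp, of phosphofructokinase, was 3.79-fold lower and then 5.49-fold higher, but both of its other probe sets went the opposite way at day 8. Wnt targets had a median of 0.56 at day 6 (percentile 99.7) and of -0.69 at day 8 (percentile 0.03), which ran from 0.07 to 0.83 and from -1.02 to -0.27 over the alternatives, with Sp5 6.70-fold higher and then 3.33-fold lower and Lef1 2.63-fold higher and then 2.69-fold lower. No Wnt target passed either adjustment in the limma fit of the mean difference, in which genes that go opposite ways could hardly pass. Of the endoderm genes, Sox17 was 2.23-fold higher and then 3.20-fold lower, and Cxcr4 1.32-fold higher and then at least 5.27-fold lower. In all, 80 genes were 2-fold apart in opposite directions (34.3 for independent lists), and across 11599 genes the MPA differences of both days correlated at r = 0.06 and rho = 0.06. Genes are not independent replicates. In a limma fit over all 5 arrays, with day as a straight line and the MPA difference free at each day, 0 of 11599 genes passed for a difference between the days (lowest adjusted p 0.919, and 0.34 to 0.966 over the alternatives), and 425 had an unadjusted p under 0.05, where 580 would be expected by chance. This fit was added after seeing the data, and a bend of the control time course counts as error in it. Its result therefore does not show that the MPA differences of both days are alike.

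The MPA differences were also set against the control time course, using only differences that share no array. Of 2016 genes 2-fold apart between day 5 and the day 8 control, 826 (41.0%, Wilson 95% interval 38.8 to 43.1) went the opposite way in the MPA difference of day 6. Of 1129 genes 2-fold apart between day 5 and the day 6 control, 528 (46.8%, 43.9 to 49.7) went the opposite way in the MPA difference of day 8. In the control step up to the day of the MPA difference, 30.4% and 7.97% of these genes were 2-fold apart the same way. The intervals treat genes as independent, which they are not. Across genes, the MPA difference of day 6 correlated with the control difference of day 8 from day 5 at r = 0.14 and rho = 0.16 over 11087 genes, and that of day 8 with the control difference of day 6 from day 5 at r = 0.02 and rho = 0.04 over 11105 genes. With that of both MPA differences, 3 correlations between differences were computed.

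Some genes of interest differed little or lay near the floor. Pou5f1 differed by a log2 of -0.16 at day 6, and Nanog was 2.76-fold lower at day 6 and under the floor on both day 8 arrays. Fkbp5, a steroid receptor target, differed by 0.06 and -0.43. Pdx1, of pancreatic progenitors, had signals of 78.6 and 90.4 at day 8, Ins2, of insulin, 92.52 and 123, and Afp 119.8 and 73.99, without and with MPA. Ins1 and T were not analysed here.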

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

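The tests of the pattern weighed in this part were all chosen only after the result was seen. With 1 array per group, the results named here are those, among the lists and the genes named in the text, whose MPA difference lay on opposite sides of 0 at day 6 and day 8, at least 2-fold each way for genes and outside the central 95% each way for lists. The difference between the days was not tested for the lists. For the genes it was tested in the limma fit with day as a straight line, where 0 of the 13 passed (adjusted p 0.919 for each) and 10 had an unadjusted p under 0.05, from a choice of genes made for their opposite directions. The value given is the MPA difference at day 8 minus that at day 6, on the log2 scale, taken directly from the arrays. The fit instead sets the MPA arrays against the fitted line of the controls, so the quantity it tested differs. Its estimates were 4.29 for Bnip3, 2.44 for Aldoc, -2.65 for Sp5 and -1.72 for Lef1, nearer to 0 than the values below. For Ier3 the estimate was 4.32, further from 0. For lists it was 2.08 for glycolysis and hypoxia and -1.25 for Wnt targets, whose day 6 median was 0.07 with a floor at the 75th percentile and up to 0.83 under the other alternatives. It was 5.18 for Bnip3, 4.38 for Pfkp, 4.02 for Aldoc, 3.70 for Ankrd37, 3.27 for Egln3 and 3.05 for Ddit4, all induced by hypoxia or part of glycolysis. It was -4.48 for Sp5 and -2.82 for Lef1, both Wnt targets, and -2.83 for Sox17 and -4.70 for Msx1. It was 4.17 for Cxcl12, 4.10 for Shisa3 and 3.89 for Ier3. For Pfkp, both other probe sets went the opposite way at day 8.

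Glycolysis and hypoxia genes were lower with MPA at day 6 and higher at day 8. Array scaling would need a shift of all genes of like size. The median over all measured genes was 0.02 at day 6 and -0.0230 at day 8. Each array had been scaled to the same trimmed mean, which would take up such a shift, so this median does not decide it. Over the alternatives, quantile normalization and median centring among them, the list's median ran from -1.61 to -1.10 at day 6. At day 8 it ran from 0.73 to 0.91. These ranges argue against the choice of scaling as the source of the pattern. Control and MPA arrays exchanged at 1 of the days would turn most other lists too, if their MPA differences were alike at both days. Of the 7 other lists apart at both days, 6 (85.7%) went the same way at both, which argues against an exchange on that condition. The pancreatic progenitor and foregut list, 1 of the 6, turned at day 6 with floors at the 65th and 75th percentiles. Single genes favour neither order, with 88 genes 2-fold apart the same way, 80 in opposite ways and r = 0.06 across genes. An effect that depends on the length of exposure, with a change of 2.08 between the days, stays open, as does an untested difference between single cultures, since there are no replicate cultures to give the spread. From day 6 to day 8 the list's median difference was -1.49 in the controls and 0.67 in the MPA cells. The larger part of the change between the days thus lay in the controls.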

How the results depend on the processing

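With 1 array per group no spread between replicates sets a limit, so a list median counts as close within 1 SD of random lists and a gene's difference within its error scaled from the limma fit. Of 1274 alternative values of list medians, 1012 stayed close to the main value, 254 moved and 8 that had stood outside the central 95% changed sign. With those inside that range, which count among the close or moved ones, 83 changed sign. Of 3059 for named genes, 2718 stayed close, 334 moved and 7 lost the test's threshold, and 16 of the close or moved ones changed sign, none of them of a difference that had been 2-fold. Of 293 counts of members adjusted over the list alone, 255 stayed within 1.5 times. These include counts of 0 that stayed 0, as in the many lists without a passing member in any setting. Counts of lists with passing members could move widely, from 0 to 8 for neural, 1 to 7 for p53 targets, 2 to 7 for epithelial and 0 to 5 for endocrine genes. A low floor lets dim probe sets, near the background, into the counts of 2-fold genes, and the cause of the other moves was not tested.

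Counts of 2-fold genes are given in the order MPA day 6, MPA day 8, control day 6 against 5, day 8 against 5 and day 8 against 6, and were 877, 870, 1244, 2157 and 1732. They were 4684, 4774, 5285, 6225 and 5775 with the floor at the 25th percentile, where dim probe sets enter, and 251, 236, 438, 961 and 682 with that at the 75th, which was chosen after seeing the data. At the 65th percentile they were 496, 475, 765 and 1142 without the fourth, which stayed within 1.5 times (1544). With the mean over probe sets they were 509, 507, 760, 1367 and 1066. Genes 2-fold apart the same way at both days numbered 88, against 1040 (25th), 34 (65th), 14 (75th), 52 (mean over probe sets) and 58 (log2(signal + floor)). Genes apart in opposite ways numbered 80, against 1049, 44 and 28 at those floors and 37 with the mean over probe sets.

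The correlation of both MPA differences (0.06) was 0.0132 at the 25th percentile floor. That of MPA day 8 with the control difference of day 6 (0.02) was -0.0028 there, and that of MPA day 6 with the control difference of day 8 (0.14) was 0.0446 there, 0.18 at the 65th and 0.23 at the 75th. The limma count of 1 became 0 under quantile normalization, the mean over probe sets, the 75th percentile floor, day as a straight line, no day term, eBayes without trend and robust, and no filter. The adjusted p of Fgfbp3 was then 0.153, 0.778, 0.114, 0.989, 0.9997, 0.764 and 1, and over the other alternatives it lay between 0.00877 and 0.0376. Its mean difference with the straight line was -2.27.

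Among list medians, pancreatic progenitor and foregut at day 6 turned to -0.22 and -0.26 at the 65th and 75th percentile floors, ribosomal proteins at day 6 to 0.0171 under quantile normalization, and BMP and TGF-beta targets at day 8 to -0.0402 with the mean over probe sets. The mean MPA difference with 1 day left out ran from -0.52 to 0.0162 for ribosome biogenesis, from -0.49 to 0.0117 for G1/S, from -1.21 to 0.0756 for cholesterol synthesis and from -0.567 to 0.0419 for retinoic acid and Hox. With the other membership rule the medians were 0.39 and 0.42 for definitive endoderm (days 6 and 8), -0.69 for neural at day 6, and, at day 8, 0.42 for p53 targets, -0.48 for Wnt targets, 0.00 for BMP and TGF-beta and 0.12 for endothelial and blood.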

Other observations

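Of the tests in this part, only those of a slower time course by genes were chosen before the result was seen, and those of array scaling or probe set choice at each day, of array scaling alone, of a slower time course by lists or of neural genes, of fewer neural cells and of general stress only after it. The cells with MPA also differed from day 6 to day 8, a comparison added after seeing the data. Cardiac muscle genes were higher at day 8 by a median log2 of 3.24, and endocrine genes by 2.52, with all 14 higher (percentile 100 for both). Mesenchymal genes were higher by 1.14 and neural genes by 0.89 (percentiles 100 and 99.9), against 1.85 for neural genes in the controls. Cholesterol synthesis genes were higher by 0.71 with MPA where their median was -0.63 in the controls, and glycolysis and hypoxia genes stood at 0.67 with MPA and -1.49 in the controls. All 23 mitosis genes were lower, with a median of -0.87.

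The remaining lists are given as medians of MPA minus control at day 6 and day 8 with percentiles. BMP and TGF-beta targets stood at 0.24 and 0.34 (94 and 99.4; -0.04 at day 8 with the mean over probe sets), and Bmp2 was the 1 member to pass the limma test adjusted over the list alone, 2.51-fold and 2.07-fold higher, against 0 over all genes and a list-alone range of 0 to 1. Steroid receptor targets stood at 0.16 and 0.20 (84.3 and 95.4), and adjusted over the list alone Sgk1 passed, 2.000-fold and 2.12-fold higher, as did Zbtb16, 3.54-fold and 2.42-fold lower, against 0 over all genes and a list-alone range of 0 to 2. Hepatic genes stood at 0.31 and 0.04 (96 and 59.2). The median of their mean difference over both days was 0.70, with 9 of 9 members higher (percentile 100), and ran from 0.00513 to 0.81 over the alternatives. Extraembryonic endoderm genes stood at 0.02 and 0.26 (59 and 98.5), intestinal and hindgut at 0.59 and 0.35 (94.5 and 88.9), and exocrine pancreas, over 3 and 4 members, at -0.04 and -0.12 (53 and 38.6). Endothelial and blood genes stood at -0.05 and -0.27 (42.6 and 18.2), Hedgehog signalling at 0.00 and -0.17 (47.5 and 19.2), and FGF and ERK targets at 0.27 and 0.08 (95.9 and 76.5). Interferon response genes stood at 0.40 and 0.17 (94.6 and 81.6), and lysosome and autophagy genes at -0.02 and 0.22 (44.1 and 98.8). Histone genes had 3 measured members at day 8 only, at 0.28 (84.2). Over the alternatives the medians of day 6 and day 8 ran from 0.12 to 1.27 and -0.58 to 0.50 for hepatic, -0.09 to 0.05 and 0.13 to 0.29 for extraembryonic endoderm, 0.48 to 0.88 and 0.30 to 0.62 for intestinal and hindgut, -0.33 to -0.04 and -1.03 to -0.00462 for exocrine pancreas, -0.48 to 0.06 and -0.27 to 0.51 for endothelial and blood genes. For the signalling lists they ran from 0.13 to 0.34 and -0.04 to 0.63 for BMP and TGF-beta, 0.06 to 0.16 and 0.10 to 0.45 for steroid receptor, -0.13 to 0.14 and -0.39 to -0.05 for Hedgehog, 0.16 to 0.45 and 0.02 to 0.17 for FGF and ERK, 0.15 to 0.44 and 0.08 to 0.22 for interferon and -0.13 to 0.04 and 0.01 to 0.26 for lysosome and autophagy genes, and from 0.04 to 0.40 for histones at day 8. No member of the lists from hepatic to histone genes passed either adjustment, with a list-alone range of 0 to 1 over the alternatives for Hedgehog signalling.

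Neural genes were lower with MPA at both days. Array scaling alone is argued against, since the median nearest to 0 under quantile normalization or median centring was -0.98, and so is probe set choice or the floor at day 8, where the median nearest to 0 over the alternatives was -0.69, while at day 6 it stays open, with -0.32 within the spread of random lists of the bound of -0.3. A lag of the whole culture as the only cause would turn lists against the control step up to that day. Of the lists apart both in that step and with MPA, 3 of 5 at day 6 (60%) went on in the direction of the controls. At day 8, 5 of 9 (55.6%) did, cardiac and endocrine genes among them. These lists argue against a lag as the only cause. The others, 2 at day 6 and 4 at day 8, went the opposite way. They included retinoic acid and Hox genes at day 6, and neural, definitive endoderm and ribosome biogenesis genes at day 8. A lag beside other differences therefore stays open. The 41.0% and 46.8% of time course genes that went the opposite way at day 6 and day 8 decide little. Only 30.4% and 7.97% of those genes were 2-fold apart the same way in that control step. A lag of neural genes would leave the MPA cells between the controls of that step. At day 6 the control step was only 0.07, with 7 of 14 members higher, within the spread of random lists (0.21). With no clear step to delay, the comparison of day 6 could not have favoured a lag. The list's median with MPA lay -1.01 from day 5 (9 of 11 lower, -1.16 to -0.45 over the alternatives). A lag alone would not place it under day 5. A lag of neural genes stays open at day 8, where the median lay -0.74 from the day 6 control (8 of 15 lower) and 0.12 with a floor at the 75th percentile. Fewer neural cells in the MPA cultures may also account for the pattern, but the list's members would then be lower by a like factor, and the middle part of the day 8 differences spanned 2.16 on the log2 scale, from -2.86 to -0.71, which does not decide it.

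Targets of p53 were higher with MPA at both days, a candidate explanation for which is a p53 response to MPA. General stress was tested only through the lists of the amino acid and integrated stress response and of the unfolded protein response. Their medians were under 0 at both days, the highest at -0.30, which argues against these responses. Other kinds of stress were not tested and stay open. Array scaling alone would need a shift of all genes of like size. The median over all measured genes was 0.02 at day 6 and -0.0230 at day 8. Each array had been scaled to the same trimmed mean, which would take up such a shift, so this median does not decide it. In a first test, the list's lowest median under quantile normalization or median centring was 0.66 at day 6, which argues against scaling there. At day 8 it was 0.29, above a bound of 0.2 by less than the spread of random lists (0.098), so that test did not decide. The day 8 median was 0.29 under quantile normalization and 0.32 under median centring, against a main value of 0.32. Such small moves argue against the choice of scaling as the source of the day 8 median. Probe set choice or the floor is argued against at day 6, where the lowest median over the alternatives was 0.66, and stays open at day 8, where it was 0.23, as close to that bound, and whether p53 itself was active in the cells was not tested.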
